A study of Gallus gallus with 6 samples.

How the data were processed

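The deposited gene table gives, per the file headers, 6 columns of estimated counts (expected counts, 7.98% of which are not whole numbers) and 6 columns of FPKM (fragments scaled to transcript length and library size), which the authors computed. The submitters' processing notes name fastp 0.18.0, Bowtie2, HISAT2, StringTie and DESeq2 without their roles. The genome build and the counting step are not given in the sources used here. The labels name total RNA extracted with TRIzol and a small RNA library kit, although the table holds genes of all lengths.

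Total counts per library were 16056240, 17289705 and 18106651 in CT replicates 1, 2 and 3 and 17250856, 17687232 and 11833015 in MP_FOS replicates 1, 2 and 3. The table lists 17623 genes, 16568 with Ensembl identifiers and 1055 assembled loci, of which 1157 had a count of 0 in all 6 libraries. Symbols are those of the file for 12776 genes, and 1140 further genes took the symbol of the NCBI gene identifier in their description. Some file symbols are older or differ from the reference, such as Wpkci-7 (HINTW), Nnf1 and TFR2 (matched to the list through the reference symbol TFRC).

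Counts were rounded and tested in R 4.3.3 with edgeR 4.0.16: filterByExpr with the group, TMM normalization, and a quasi-likelihood F test with default settings of MP_FOS against CT, two-sided. Benjamini-Hochberg (BH) adjustment ran over the 13774 genes that passed the filter, and the threshold was an adjusted p of 0.05 with no minimum fold change. The common biological coefficient of variation was 0.264. Printed CPM are normalised by TMM. DESeq2 1.42.0 (Wald test, default settings) and limma 3.58.1 (voom) were run as other tools.

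The contrast, the gene lists, the rule for named genes and most alternatives were set before the data were examined. Gene lists with at least 5 tested members and annotation terms with 10 to 500 tested genes were tested with camera on log2 CPM, with a preset correlation of 0.01, and BH over the lists or over the terms of each annotation. Camera was repeated with an estimated correlation, and fry was run on the lists. List medians per library are medians over members of log2 CPM minus the CT mean of the gene. Principal components used the 500 most variable genes.

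The rule for named genes asked first for up to 12 genes per direction past the threshold, with a gene symbol, no overlap between the groups and a mean of at least 5 CPM in the higher group. As no gene passed, its fallback took the 5 of each direction with the smallest unadjusted p under the other conditions. It then took up to 4 members that passed, or otherwise the 2 with the smallest p, from each list, and the W-linked genes. The rule excludes assembler identifiers, which was read, after the values were seen, as leaving assembled loci out of the first part even where the file gives them a symbol. This left out BTN1A1 (1 of several loci with this symbol, higher, DESeq2 log2 fold change 1.19) and SMIM32 (lower, −1.11), which would otherwise be among the 10. Assembled loci were kept in the lists, among them Muc2, NFIL3 and FLNC. Genes named outside the rule are said to be so where they appear.

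Simulated negative binomial counts, 5 sets of 13774 genes with the CT means and the per-gene spread of these libraries, served as a test of the code. A simulated list of 30 genes shifted by 0.5 (log2) was called by camera in 5 of 5 sets, and unchanged lists in 0 of 200. Genes were drawn independently of each other, so this does not show how often camera calls unchanged lists of genes that vary together.

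Alternatives were DESeq2 size factors and upper-quartile factors in place of TMM, no filter or a stricter one (at least 1 CPM in 3 libraries), a robust edgeR fit, adjusted p of 0.01 or 0.1, a minimum log2 fold change of 1, limma-trend on log2 FPKM with a pseudocount of 1 or 0.1, the replicate number as a block, and leaving out each library. Added after seeing the data were the W-linked signal as a covariate in edgeR and in DESeq2, both libraries without W-linked reads left out, a loess of log2 CPM on transcript length removed from each library, and a second robust edgeR fit. Transcript length came from the ratio of count to FPKM.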

Results

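Ileum of Taiping chickens aged 2 months was sequenced in 6 RNA libraries, to ask how a probiotic given with fructo-oligosaccharide (FOS, short fructose chains that gut bacteria ferment) alters gene expression in the distal small intestine. The 3 CT libraries came from birds on a corn-soybean basal diet. The 3 MP_FOS libraries came from birds whose drinking water also carried 2 mL of probiotics and 1 mL of FOS per litre. The deposited expected counts summed to between 11833015 (MP_FOS replicate 3) and 18106651 (CT replicate 3) per library, so that 1 count stood for 0.0531 to 0.0843 normalised CPM (counts scaled to a common library size). Of 17623 listed genes, 13774 passed the low-count filter and were tested. The labels number the replicates without stating that each is a separate bird, so the p-values measure the spread between these samples. Values are normalised CPM as mean ± SD over the 3 libraries of a group, and log2 fold changes (MP_FOS minus CT, edgeR) carry an SE. This SE is the absolute log2 fold change divided by the square root of the test's F statistic. Where a value stands against another, CT comes first and MP_FOS second.

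Interferon-stimulated genes and cholesterol synthesis genes stood higher in MP_FOS ileum, and matrix genes and enteric neuron genes stood lower, but MP_FOS replicate 1 stood near CT in the interferon, cholesterol, cytokine, mitochondrial-encoded and xenobiotic lists (medians between −0.08 and 0.12 against the CT mean). The interferon, cholesterol, matrix and neuron lists did not pass camera with an estimated correlation between genes (adjusted p from 0.416 to 0.911, BH). Correlation of log2 CPM across genes, which are not independent replicates, ran from 0.939 to 0.976 within groups and from 0.942 to 0.972 between them. The first principal component of the 500 most variable genes held 44.6% of their variance. It set MP_FOS replicate 2 (43.2) and CT replicate 2 (25.1) apart from the other 4 libraries, which lay between −22.3 and −10.8.

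All 6 libraries are labelled male, yet 4 of them held transcripts of the W chromosome, which hens carry and cocks lack. Wpkci-7, the W-linked HINTW, had 2438 and 2804 reads in CT replicates 1 and 3 and 2047 and 1846 in MP_FOS replicates 1 and 3. It had 3 in CT replicate 2 and 0 in MP_FOS replicate 2. SPIN1W, HNRNPKL and ATP5F1AW, the other members of the W-linked list that were measured, split the libraries in the same way, with at most 4.06 reads in the replicates numbered 2. Each diet thus had 2 libraries with W-linked reads and 1 without. The libraries without them, CT replicate 2 and MP_FOS replicate 2, were those that the first principal component set apart.

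**Figure D1:**
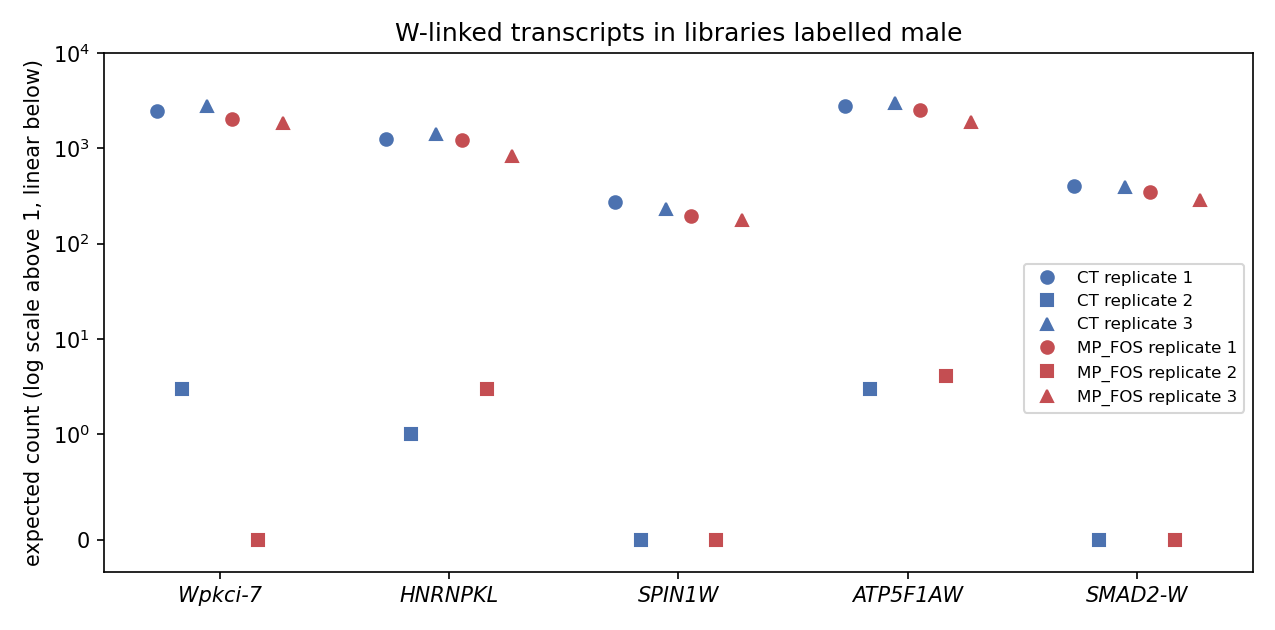
Read counts of 5 W-linked genes (y axis, expected count, log scale above 1 and linear below) in the 6 ileum libraries, 1 point per library, coloured by diet. The 4 libraries with W-linked reads hold between 175 and 3005 reads of each gene, against 0 to 4.06 in CT replicate 2 and MP_FOS replicate 2.

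IL8 (ENSGALG00000026098), a chemokine that draws heterophils, had 1.49 ± 0.186 CPM in CT and 12.3 ± 4.64 CPM in MP_FOS, a log2 fold change of 3.05 ± 0.36. The other 4 genes of higher mean with the smallest unadjusted p were HES6 (ENSGALG00000048261), a Hes-family transcription factor, at 87.4 against 149 CPM, RHPN1 (ENSGALG00000034337) at 136 against 250 CPM, ENTPD8 (ENSGALG00000008932), which splits extracellular nucleotides, at 5.74 against 21.9 CPM, and Nnf1 (ENSGALG00000046965), a kinetochore protein, at 25.1 against 48.8 CPM. Their log2 fold changes were 0.77 ± 0.12, 0.88 ± 0.15, 1.94 ± 0.34 and 0.96 ± 0.18. Among the 5 of lower mean were CD93 (ENSGALG00000008359), PTPRB (ENSGALG00000010049) and angiopoietin-2 (ENSGALG00000036189), all products of blood vessel endothelium, with log2 fold changes of −0.83 ± 0.13, −0.66 ± 0.11 and −0.77 ± 0.13. PI16 (ENSGALG00000000560), a fibroblast marker, had 21.5 ± 2.17 CPM in CT and 9.14 ± 1.69 CPM in MP_FOS, and Nox4 (ENSGALG00000017235), an oxidase that makes hydrogen peroxide, had 21.7 ± 1.11 CPM in CT and 10.8 ± 1.32 CPM in MP_FOS. In none of these 10 genes did the 3 libraries of one diet overlap those of the other. The unadjusted p-values in edgeR ran from 5.10e-05 (IL8) to 0.000892 (Nnf1), and none of the 10 passed after Benjamini-Hochberg (BH) adjustment over all genes tested (adjusted p = 0.445 for each). Without MP_FOS replicate 1, IL8, HES6, RHPN1 and CD93 passed (edgeR adjusted p = 0.0133, 0.0401, 0.0442 and 0.039, BH). In each of these genes the library left out was the MP_FOS library nearest to CT, so its removal favours a pass.

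**Figure D2:**
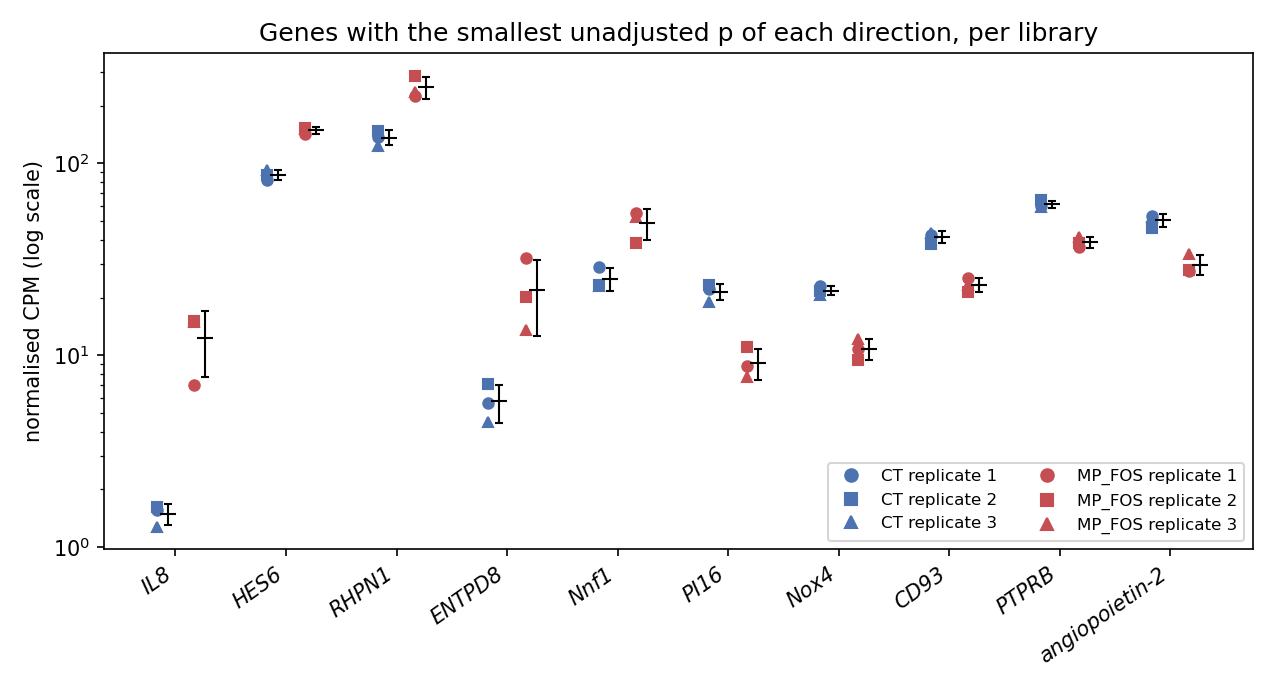
Normalised CPM (y axis, log scale) of the 5 genes of each direction with the smallest unadjusted p, 1 point per ileum library with the mean and SD of each diet beside the points. CT and MP_FOS points do not overlap for any of the 10, and IL8 runs from 1.27 to 1.62 CPM in CT and from 6.99 to 15.0 CPM in MP_FOS.

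With edgeR's quasi-likelihood test, 0 of 13774 genes passed an adjusted p of 0.05 (BH), 1457 had an unadjusted p under 0.05 (788 higher and 669 lower in MP_FOS, where chance gives 689 on average), and the smallest adjusted p was 0.445. Splits of the 6 libraries 3 against 3 that mix the diets gave up to 1156 genes with an unadjusted p under 0.05, so the excess over 689 is not by itself a diet effect. DESeq2 gave 104 genes (68 higher, 36 lower), all 10 named above among them, and limma-voom gave 0. Without MP_FOS replicate 1, edgeR gave 223 genes (180 higher, 43 lower), of which 46 were also among DESeq2's 104. The groups did not overlap in 2299 genes, 16.7% against 10% by chance. That chance value is an average over groupings of the libraries, and its spread was not computed. Simulated counts had the CT means and the per-gene spread of these libraries. In them, edgeR recovered 80.4% of 4-fold and 27.4% of 2-fold changes with 10.8 false calls per set, and DESeq2 recovered 87.2% and 53.6% with 44.6 false calls. Genes were simulated independently, without shifts that many genes of a library share, so this recovery need not hold for the real libraries.

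Of 34 gene lists fixed beforehand with enough measured members, 9 passed camera, which tests a list against all other genes (adjusted p under 0.05, BH over the lists, preset correlation between genes of 0.01). Of these 5 rose and 4 fell in MP_FOS. Of the 10 even splits of the 6 libraries, 6 gave at least 9 lists, the real one included, and the highest of the others gave 12. With the correlation estimated from the data, 0 of the 9 passed after adjustment, and fry, which asks whether a list's genes move one way, gave 1, the matrix list (adjusted p = 0.0491). No member of any list passed edgeR over all genes, so members are given as values. Without MP_FOS replicate 1, 12 list members named by the rule other than IL8 passed in edgeR (adjusted p, BH): IFI27L1 (0.0133), CYCS (0.0251), LYG2 (0.0286), IL22 (0.0296), SLC10A2 (0.0302), TXNRD1 (0.0304), LYZ (0.031), LGR5 (0.031), MUC13 (0.031), SLC5A8 (0.0334), HLF (0.0405) and IRF8 (0.0493). In each of these 12 genes replicate 1 was the MP_FOS library nearest to CT, so its removal favours a pass. DESeq2 called 10 with all 6 libraries, namely IL22, LYZ, SLC10A2, HLF, CTSS, Muc2, EGR1, CYCS, ADH1C and SULT1C3. MX1, IRF1, IRF7, FDFT1, SQLE, IL1B, CCL17, CCL21, COL6A3, COL5A1, FN1, NOS1, GAL, CYP2C18, TF and EXFABP lie outside the rule for named genes and were chosen after their values were seen.

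Interferon-stimulated genes, the antiviral programme that interferons switch on, rose in MP_FOS as a list. All 31 measured members were higher, with a median log2 fold change of 1.02 (quartiles 0.76 to 1.75). When adjusted over the list alone, 10 passed edgeR, all of them narrowly (smallest adjusted p = 0.0493, BH). IFI6 averaged 118 ± 74.3 against 859 ± 763 CPM, IFI27L1 53.9 ± 11.7 against 259 ± 173 CPM, and MX1, a GTPase that interferon induces, 72.4 ± 11.3 against 273 ± 229 CPM. IRF7 and IRF1, transcription factors of the pathway, stood at 111 against 225 CPM and 279 against 574 CPM. The list median against the CT mean was −0.08, 1.62 and 1.08 in MP_FOS replicates 1, 2 and 3, so replicate 1 lay at the CT level. Camera gave an adjusted p of 3.37e-11 (BH), against an adjusted p of 0.911 with an estimated correlation (unadjusted p = 0.191). Without MP_FOS replicate 2, one of the 2 libraries that lacked W-linked reads, the median fold change was 0.58.

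Cholesterol synthesis genes rose as a list, with 21 of 22 members higher and a median log2 fold change of 0.66. CYP51A1, a demethylase of the sterol nucleus, averaged 40.1 ± 6.25 against 93.3 ± 49.6 CPM, and DHCR7, of a late step to cholesterol, 12.4 ± 0.617 against 19.7 ± 3.82 CPM. FDFT1 (squalene synthase) and SQLE (squalene epoxidase) stood at 51.6 against 120 CPM and 15.8 against 42.5 CPM. Camera gave an adjusted p of 8.88e-07 (BH), and an adjusted p of 0.911 with an estimated correlation. MP_FOS replicates 1, 2 and 3 had list medians of 0.12, 1.19 and 0.46 against the CT mean, and the median fold change was 0.28 without MP_FOS replicate 2 and 0.22 with both libraries that lack W-linked reads left out (adjusted p = 0.0138).

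Cytokine and chemokine genes rose as a list (21 of 30 higher, median log2 fold change 0.33), and 3 members passed edgeR adjusted over the list alone, all of them higher: IL8, IL22 and CCL17. IL22, which drives epithelial defence and repair, averaged 2.42 ± 0.849 against 16.6 ± 11.9 CPM, with 5.13, 29.0 and 15.8 CPM in MP_FOS replicates 1, 2 and 3. CCL17, a ligand of CCR4, stood at 1.41 against 3.13 CPM, and IL1B at 1.27 against 3.23 CPM. CCL21, which guides lymphocytes into lymphoid tissue, went the other way at 179 against 86.7 CPM. Camera's adjusted p was 0.00549 (BH), and the adjusted p with an estimated correlation was 0.911. The call was lost without MP_FOS replicate 3 (median 0.15, adjusted p = 0.0751), and with both libraries that lack W-linked reads left out (median 0.33, adjusted p = 0.121). MP_FOS replicates 1, 2 and 3 had list medians of −0.06, 0.49 and 0.63 against the CT mean, so replicate 1 lay at the CT level, and without it the median fold change was 0.54.

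Antigen presentation genes rose as a list by a median log2 fold change of 0.28 (15 of 20 higher), the 3 MP_FOS libraries lying at 0.24, 0.19 and 0.29 against the CT mean. CTSS, a cathepsin that trims the class II invariant chain, averaged 639 ± 47.1 against 925 ± 71.1 CPM, and CD40 averaged 26.0 ± 2.66 against 35.4 ± 5.64 CPM. Camera's adjusted p was 0.0213 (BH), against an adjusted p of 0.444 with an estimated correlation. The call was lost without CT replicate 3 (adjusted p = 0.0584), without MP_FOS replicate 1 (0.108) and without MP_FOS replicate 3 (0.0603). Over 14 alternatives the list median ran from 0.19 to 0.29.

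Nuclear genes of oxidative phosphorylation rose slightly and together (34 of 37 higher, median log2 fold change 0.21). CYCS, the electron carrier cytochrome c, averaged 49.8 ± 3.98 against 94.0 ± 27.2 CPM, and NDUFS3, a complex I subunit, 44.4 ± 3.54 against 65.6 ± 13.2 CPM. Genes encoded by the mitochondrial DNA fell, with 12 of 13 lower and a median of −0.31 (−0.01, −0.71 and −0.47 in MP_FOS replicates 1, 2 and 3). ND2 averaged 1102 ± 156 against 728 ± 181 CPM, and ND4L averaged 44.4 ± 5.65 against 29.4 ± 6.60 CPM. Mitochondrial transcripts made up 3.94, 3.77 and 4.71% of counts in CT replicates 1, 2 and 3 and 4.12, 2.58 and 3.14% in MP_FOS. Camera's adjusted p-values were 1.23e-05 and 0.000537 (BH), and the adjusted p-values with an estimated correlation were 0.646 and 0.911. Without MP_FOS replicate 2 the medians were 0.13 for the nuclear and −0.14 for the mitochondrial genes, and the latter was −0.57 without MP_FOS replicate 1 and −0.19 without CT replicate 3. Across all genes, the median log2 fold change went from 0.07 in the shortest of 4 equal bins of transcript length to −0.06 in the longest, and oxidative phosphorylation genes had a median length of 1152 bases against 3717 for the matrix genes described next.

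Fibroblast and matrix genes fell in MP_FOS as a list, and the 3 MP_FOS libraries were alike here, with medians of −0.35, −0.31 and −0.48 against the CT mean. Of 28 members 25 were lower, 18 of them without overlap between the groups, and the median log2 fold change was −0.36 (quartiles −0.46 to −0.30). Over all tested genes 16.7% did not overlap, in either direction, where chance gives 10% on average. PDGFRA and PDGFRB, growth factor receptors of mesenchymal cells, averaged 108 ± 11.2 against 69.4 ± 11.5 CPM and 34.7 ± 2.28 against 24.3 ± 2.30 CPM. COL6A3, COL5A1 and FN1, which encode collagens and fibronectin, stood at 477 against 342 CPM, 172 against 125 CPM and 772 against 563 CPM. Camera's adjusted p was 1.43e-09 (BH). With an estimated correlation the p was 0.0122 unadjusted and 0.416 adjusted.

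Genes of enteric neurons and glia, the cells of the gut's own nervous system, fell as a list, with 23 of 24 members lower and a median log2 fold change of −0.51. SYT1, a calcium sensor of synaptic vesicles, averaged 3.03 ± 0.238 against 1.5 ± 0.281 CPM, and CHRNA3, a nicotinic receptor subunit, 7.60 ± 1.83 against 4.27 ± 0.144 CPM. NOS1 and GAL, which mark inhibitory and peptidergic neurons, stood at 8.13 against 3.93 CPM and 32.6 against 19.9 CPM. Camera's adjusted p was 2.03e-06 (BH), against an adjusted p of 0.444 with an estimated correlation (unadjusted p = 0.0361). MP_FOS replicates 1, 2 and 3 had medians of −0.18, −0.41 and −0.79 against the CT mean. Smooth muscle genes, which share the outer gut wall with the nerve plexus, had a median log2 fold change of −0.09 and did not pass (adjusted p = 0.554, BH, camera). Without CT replicate 2 or MP_FOS replicate 3 the smooth muscle list was called lower, with medians of −0.15 (adjusted p = 0.0158) and −0.21 (adjusted p = 0.0329), while its median was above 0 without CT replicate 3 (0.09, adjusted p = 0.780) or MP_FOS replicate 2 (0.02, adjusted p = 0.778). FLNC averaged 15.3 ± 3.37 against 8.90 ± 1.07 CPM and HSPB7 7.34 ± 3.44 against 18.6 ± 11.3 CPM.

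Xenobiotic metabolism genes fell as a list (19 of 22 lower, median log2 fold change −0.30). ADH1C, an alcohol dehydrogenase that also oxidises retinol, averaged 31.8 ± 12.5 against 5.59 ± 3.96 CPM, and SULT1C3, a sulfotransferase, 480 ± 29.9 against 231 ± 89.6 CPM. Together with CYP2C18 they passed edgeR adjusted over the list alone, all 3 of them lower. Camera's adjusted p was 0.000642 (BH), against an adjusted p of 0.911 with an estimated correlation. The medians of MP_FOS replicates 1, 2 and 3 were 0.07, −0.48 and −0.83 against the CT mean, and the median fold change was −0.92 without MP_FOS replicate 1 and −0.55 with the replicate number as a block.

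**Figure D3:**
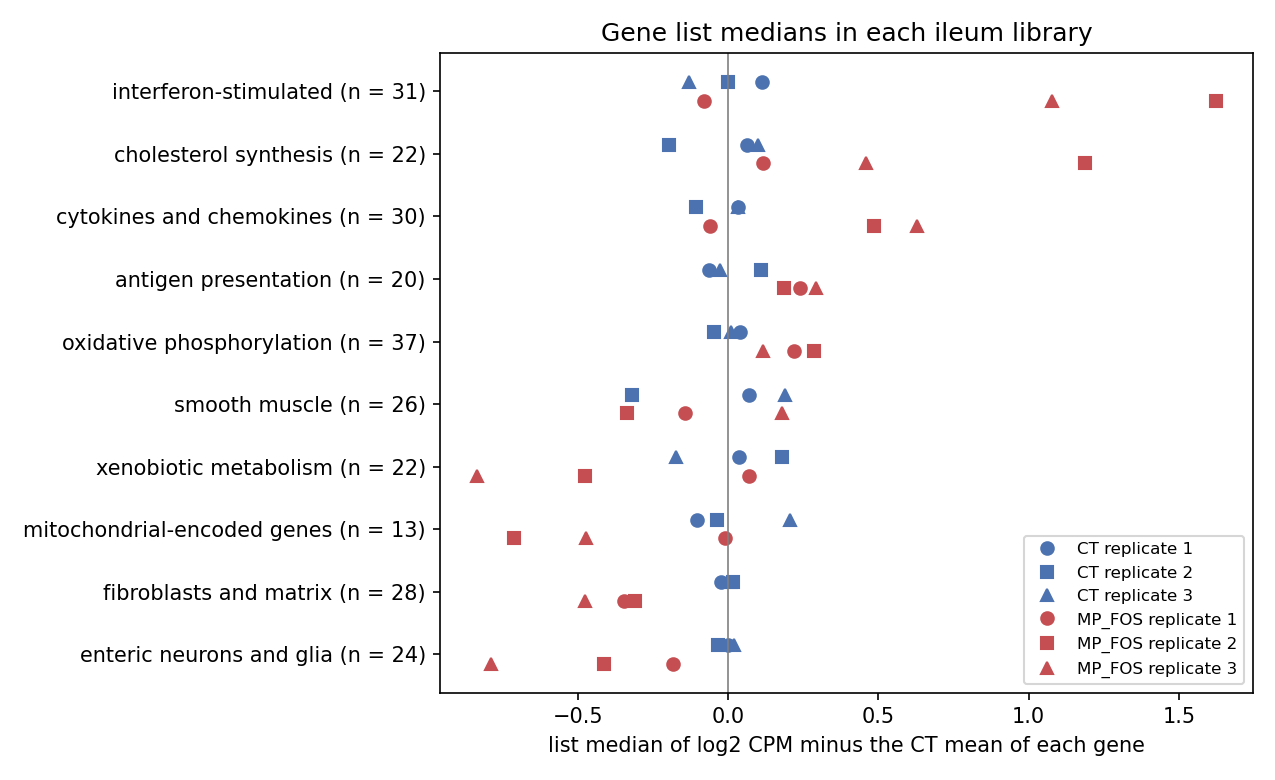
Median over the members of each of 10 gene lists (the 9 that passed camera, and smooth muscle) of log2 CPM minus the CT mean of each gene (x axis), 1 point per ileum library, coloured by diet. The 3 MP_FOS points of the matrix list lie together between −0.48 and −0.31, whereas those of the interferon list lie at −0.08, 1.62 and 1.08.

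Markers of immune cells as such did not pass camera: T and NK cells (median log2 fold change 0.10, adjusted p = 0.461, BH), B and plasma cells (−0.07, 0.461), macrophages and dendritic cells (0.07, 0.522), and heterophils and mast cells (0.37, 0.37). GZMA, a granzyme of cytotoxic lymphocytes, averaged 181 ± 112 against 480 ± 265 CPM, and CTLA4, which restrains T cells, 8.05 ± 1.15 against 15.6 ± 6.37 CPM. CXCR5 and CD72, found on B cells, averaged 6.81 ± 2.66 against 2.68 ± 0.537 CPM and 5.07 ± 1.82 against 2.06 ± 0.701 CPM. The complement gene C1QB stood at 46.9 against 77.7 CPM, IRF8 at 327 against 554 CPM and the mast cell receptor KIT at 28.6 against 19.5 CPM. The T and NK list was called higher without MP_FOS replicate 2 (median 0.18, adjusted p = 0.0237) and the B cell list lower without CT replicate 2 (median −0.12, adjusted p = 0.0391). With 1 library left out, the medians ran from 0.02 (without MP_FOS replicate 1) to 0.18 for T and NK cells, from −0.23 (without MP_FOS replicate 3) to −0.06 (without CT replicate 3) for B cells, and from 0.01 (without MP_FOS replicate 3) to 0.22 (without MP_FOS replicate 2, adjusted p = 0.0862) for macrophages.

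Antimicrobial genes went both ways, and 4 of the 10 passed edgeR adjusted over the list alone although the list did not pass camera (adjusted p = 0.674, BH). LYZ, the c-type lysozyme, averaged 44.0 ± 3.03 against 17.8 ± 6.36 CPM, and TF, the iron carrier ovotransferrin, stood at 80.6 against 53.9 CPM. EXFABP, which binds bacterial siderophores, stood at 15.8 against 44.3 CPM. LYG2, a goose-type lysozyme, had 7.15, 7.13 and 3.03 CPM in CT replicates 1, 2 and 3 and 4, 239 and 80.3 CPM in MP_FOS. Pattern recognition and NF-kB genes did not pass (median 0.08, adjusted p = 0.674), and their median ran from 0.04 to 0.14 over 14 alternatives. Within them NFKBIA, the NF-kB inhibitor, averaged 109 ± 4.98 against 147 ± 19.0 CPM and TLR5, the flagellin receptor, 8.73 ± 1.69 against 5.30 ± 0.55 CPM.

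SLC10A2, the transporter that takes up bile acids in the ileum, averaged 181 ± 18.5 against 354 ± 80.3 CPM and passed edgeR adjusted over the bile acid list alone (adjusted p = 0.0188, BH). NR1H4, the bile acid receptor FXR, averaged 97.1 ± 17.3 against 149 ± 25.6 CPM. The bile acid list did not pass camera (median log2 fold change 0.09, adjusted p = 0.461), but did without MP_FOS replicate 3 (median 0.33, adjusted p = 0.0413), and without MP_FOS replicate 1 its median was −0.11 (adjusted p = 0.877). Fat absorption and lipoprotein genes did not pass (median −0.12, adjusted p = 0.325), and were called lower without MP_FOS replicate 1 (median −0.45, adjusted p = 0.0165). Their median was above 0 without CT replicate 2 (0.04, adjusted p = 0.744) and with both libraries that lack W-linked reads left out (0.08, adjusted p = 0.963). ABCA1, a cholesterol exporter, averaged 95.3 ± 12.8 against 65.6 ± 7.63 CPM, and AGPAT2, an enzyme of triglyceride synthesis, 120 ± 10.3 against 196 ± 62.3 CPM.

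Lists of the absorptive and secretory epithelium did not pass camera. Adjusted p-values (BH) were 0.275 for tight junctions, 0.554 for goblet cells, 0.681 for nutrient transporters, 0.969 for the brush border, 0.969 for short-chain fatty acid handling, 0.897 for enteroendocrine cells and 0.461 for crypt stem cells. The crypt list was called lower with both libraries that lack W-linked reads left out (median −0.17, adjusted p = 0.0397). CLDN3 and CLDN23, claudins of the tight junction, averaged 312 ± 23.4 against 475 ± 140 CPM and 11.1 ± 2.51 against 19.2 ± 4.66 CPM. Muc2, the gel-forming mucin of goblet cells, averaged 801 ± 74.9 against 433 ± 123 CPM, and MUC13, a membrane mucin, 1101 ± 306 against 2839 ± 1637 CPM. SLC5A8, which takes up butyrate, averaged 7.73 ± 4.03 against 48.1 ± 36.9 CPM, with 5.55, 69.9 and 68.9 CPM in MP_FOS replicates 1, 2 and 3, and SLC16A7 averaged 7.66 ± 1.43 against 4.64 ± 0.31 CPM. Amino acid transporters SLC36A1 and SLC7A2 averaged 42.2 ± 1.25 against 59.8 ± 7.88 CPM and 3.22 ± 0.826 against 1.31 ± 0.256 CPM. LGR5, the stem cell receptor of the crypt, averaged 34.6 ± 3.36 against 19.8 ± 6.58 CPM, and MSI1 22.7 ± 1.32 against 26.7 ± 1.77 CPM. VIL1 and ENPEP stood at 818 against 1206 CPM and 2322 against 1557 CPM, and PCSK2 and PAX6 at 26.1 against 17.8 CPM and 2.02 against 3.33 CPM.

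Proliferation genes did not pass (28 of 31 higher, median log2 fold change 0.24, adjusted p = 0.174, BH, camera), with MCM4 at 38.0 against 51.6 CPM and MCM6 at 67.0 against 89.0 CPM. The list was called higher without CT replicate 1 (median 0.43, adjusted p = 0.00316), without MP_FOS replicate 1 (0.43, 0.000155) or without MP_FOS replicate 3 (0.38, 0.0427). It was called lower without MP_FOS replicate 2 (−0.15, 0.0267) and with both libraries that lack W-linked reads left out (−0.28, 0.000205). Ribosomal protein genes (median 0.05, adjusted p = 0.601) were called lower without MP_FOS replicate 1 (−0.13, 0.00745) and higher without MP_FOS replicate 2 (0.20, 5.93e-06) and with both W-lacking libraries left out (0.20, 0.000205), with RPL26 at 86.0 against 101 CPM and RPL12 at 533 against 639 CPM.

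Among the other lists that did not pass were the circadian clock (adjusted p = 0.656, BH, camera), immediate early and heat shock genes (0.758), antioxidant defence (0.967) and fatty acid oxidation (0.897). HLF and NFIL3, which act on the same clock promoter element in opposite ways, averaged 33.8 ± 6.87 against 16.4 ± 5.10 CPM and 8.37 ± 0.67 against 14.7 ± 2.68 CPM, and both passed edgeR adjusted over the list alone. EGR1 and FOS, which cells switch on within minutes of a stimulus, averaged 61.8 ± 14.0 against 135 ± 41.2 CPM and 103 ± 25.5 against 180 ± 39.4 CPM. TXNRD1 and GPX4, selenoenzymes, stood at 68.8 against 141 CPM and 60.3 against 43.3 CPM, and HADHA and ACOX2, of fatty acid oxidation, at 407 against 536 CPM and 69.3 against 50.7 CPM. The antioxidant list's median (−0.02) and mean (0.02) differed in sign, and the fatty acid oxidation list had a median and a mean within 0.01 of 0. Over 14 alternatives the fatty acid oxidation median ran from −0.07 to 0.13.

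Lists of neighbouring tissues and of gut position did not pass camera, with adjusted p-values (BH) of 0.681 for gut segment position, 0.811 for erythrocytes and 0.897 for liver. HOXA13 and SLC40A1, which mark distal and proximal gut, stood at 14.3 against 18.7 CPM and 120 against 93.0 CPM. CA2 stood at 67.4 against 82.9 CPM, TFR2 at 44.2 against 65.2 CPM, ITIH2 at 5.26 against 2.21 CPM and FGG at 4.75 against 10.6 CPM. Pancreas acinar and skeletal muscle lists had 3 measured members each and were not tested. Of these, ZP2 and BHLHA15 stood at 2.67 against 3.88 CPM and 4.52 against 4.74 CPM, and ACTC1 and ACTA1 at 0.814 against 2.84 CPM and 53.1 against 69.7 CPM.

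Pathway and gene ontology (GO) terms named by the deposited annotation were tested in the same way, and the 10 named here were chosen after their values were seen. Past the threshold with the preset correlation, 5 were higher and 5 lower, but none was with an estimated correlation, where their adjusted p ran from 0.276 (extracellular matrix) to 0.81 (proteasome). The proteasome, which degrades tagged proteins, stood higher (36 genes, median log2 fold change 0.28, camera adjusted p = 1.63e-07, BH), as did cytosolic DNA sensing (0.28, 2.77e-06), oxidative phosphorylation (0.22, 6.44e-06), steroid biosynthesis (0.66, 0.00228) and lymphocyte chemotaxis (0.63, 0.000838). The extracellular matrix stood lower (149 genes, −0.31, 6.87e-07), as did ECM-receptor interaction (−0.25, 0.000404), blood vessel morphogenesis (−0.32, 0.0036), enteric nervous system development (−0.43, 0.00738) and retinol metabolism (−0.32, 0.0162). In all, 28 of 150 KEGG pathways passed (18 higher, 10 lower), as did 125 of 1472 GO processes (20 and 105), 23 of 346 GO components (9 and 14) and 38 of 503 GO functions (12 and 26). With an estimated correlation 0 terms of any of these 4 annotations passed, with 9, 99, 18 and 30 at an unadjusted p under 0.05 in camera.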

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

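The covariate for the W-linked signal, the removal of the length trend, the second robust fit and the setting without both W-lacking libraries were chosen after seeing the data, and the other alternatives were planned. The count of genes past an adjusted p of 0.05 in edgeR, 0 with 1457 unadjusted, was 104 with DESeq2 and 93 with DESeq2 and the W-linked covariate, and 0 with limma-voom. Leaving out 1 library gave between 0 and 223 genes, the 223 without MP_FOS replicate 1. The cause was not tested. Without both libraries that lack W-linked reads it was 1, ENSGALG00000047837, which had 0 and 0.0531 CPM in CT replicates 1 and 3 and 43.9 and 35.2 in MP_FOS replicates 1 and 3, but 38.0 in CT replicate 2 and 0.297 in MP_FOS replicate 2. With the replicate number as a block, edgeR gave 0 genes and 9 lists, and genes with unadjusted p under 0.05 numbered 1179. The lists past the threshold went from 9 to 0 with an estimated correlation and to 1 with fry, and leaving out 1 library gave between 8 and 12. The terms went to 0 in each of the 4 annotations with an estimated correlation, which by construction widens the test for genes that vary together. GO functions went from 38 to 23 with the length trend removed, and the cause was not tested. The first principal component held 38.2% with 2000 genes and 36.3% with all tested genes, as more genes of lower variance enter.

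The 80 named genes had 1360 values under 17 settings, of which 1320 kept direction and side of the threshold, 36 newly passed (20 with DESeq2 and 16 without MP_FOS replicate 1) and 4 reversed. BHLHA15 (log2 fold change 0.07) ran from −0.34 (without CT replicate 2) to 0.41 when 1 library was left out and was also negative, at −0.05, without MP_FOS replicate 1. It was −0.25 and TFR2 −0.11 without both W-lacking libraries. The cause was not tested. The 9 called lists had 144 values, of which 122 kept their call, 22 lost it and 0 reversed. MP_FOS replicate 3 had the lowest depth, at which 1 count stood for 0.0843 normalised CPM.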

Other observations

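Chosen only after the result was seen were the tests of immune cell share, of 1 library alone, of the length trend in the neuron list, of the outer gut wall and of the endothelial list, and also the genes named in the next paragraphs.

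Several genes outside the fixed lists passed DESeq2 (adjusted p under 0.05, BH) but not edgeR with all 6 libraries. Without MP_FOS replicate 1, the 7 genes of this paragraph also passed edgeR, with adjusted p-values (BH) from 0.0137 (CD274) to 0.0306 (SOCS3). That adds no separate support, as the genes were chosen after their values were seen. The library left out also had the lowest MP_FOS value in each of them. SOCS3, which cytokines such as IL-22 induce to limit their own signal, had 45.0, 53.4 and 76.3 CPM in CT replicates 1, 2 and 3 and 125, 509 and 245 CPM in MP_FOS replicates 1, 2 and 3 (DESeq2 adjusted p = 0.000165, BH). In the same order of libraries, NOXO1, the organizer of an epithelial NADPH oxidase, had 49.7, 61.0 and 26.8 CPM in CT and 69.3, 304 and 258 CPM in MP_FOS. The EGF receptor ligands EREG and AREG had 9.19, 29.7 and 21.7 and 0.418, 5.35 and 14.2 CPM in MP_FOS, against 6.61, 4.81 and 6.06 and 0.541, 0.812 and 0.584 CPM in CT. MMP7, a matrix protease, had 1.38, 0.29 and 0.266 CPM in CT and 1.25, 34.9 and 16.9 CPM in MP_FOS. CD274, the checkpoint ligand PD-L1, had 12.6, 11.4 and 16.1 CPM in CT and 15.5, 64.6 and 69.3 CPM in MP_FOS, and IL4I1, which breaks down aromatic amino acids, 1.56, 1.28 and 2.28 and 1.85, 24.5 and 16.8 CPM. In CD274, IL4I1 and MMP7 the value of MP_FOS replicate 1 lay within the CT range, and in AREG below it.

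FABP6, the ileal bile acid binding protein, had 5753, 5173 and 4514 CPM in CT replicates 1, 2 and 3 and 6886, 1975 and 1293 CPM in MP_FOS replicates 1, 2 and 3. It did not pass edgeR adjusted over the bile acid list alone with all 6 libraries, but passed over all genes without MP_FOS replicate 1 (log2 fold change −1.66, adjusted p = 0.0341, BH). The library left out stood above every CT library, so its removal favours a pass. SLC10A2, the transporter upstream of it, had 168, 202 and 172 and 267, 425 and 371 CPM. The difference between these 2 genes was not tested.

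W-linked reads stood in 4 of the 6 libraries labelled male, SMAD2-W included, a gene found by its description after the others (406 and 392 reads in CT replicates 1 and 3, 344 and 288 in MP_FOS replicates 1 and 3, 0 in both replicates numbered 2). Reads carried over from hens would leave Z-linked genes level. However, 85 Z-linked genes had a median log2 difference of −0.41 between libraries with and without W-linked reads within diets (95% interval over genes −0.50 to −0.33). This interval does not measure the spread between birds. None of 10000 random lists of matched expression went as low. Of these genes 77 (a share of 0.906) were lower in the 4 libraries, to a median of 75.4% of the level in the other 2, in line with 4 birds of the other sex than labelled. Each diet has 1 library that lacks W-linked reads, so this does not set the diets apart, and a wrong label or a swap with birds outside the series cannot be separated by these data.

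Interferon-stimulated genes stood higher in MP_FOS by a median log2 fold change of 1.02. A larger share of lymphocytes, macrophages and dendritic cells together, as the whole source, would raise their markers alike. However, 77 members of the T, NK, B, plasma, macrophage and dendritic lists had a median of 0.048 (95% interval over genes −0.049 to 0.141). This pooled median cannot exclude a rise of 1 cell type, which markers of the others would offset. The macrophage and dendritic list stood at 0.16, −0.14 and 0.40 against the CT mean in MP_FOS replicates 1, 2 and 3. A single MP_FOS library is not the whole source of the interferon shift, since the lowest interferon median with 1 MP_FOS library left out was 0.581. A larger share of heterophils or mast cells stays open, as the 15 members of their list had a median of 0.371 (−0.125 to 0.860), which was 0.17 without CT replicate 3, 0.19 without MP_FOS replicate 2 and 0.18 without MP_FOS replicate 3. An infection in some birds, or a response to the diet in some only, may also account for this and was not tested.

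Matrix and neuron genes were lower and oxidative phosphorylation genes higher in MP_FOS, and the latter are short transcripts while the matrix genes are long. With each library's length trend removed, the list medians were −0.283 for matrix (95% interval over genes −0.312 to −0.256) and −0.508 for neurons (−0.832 to −0.210), both still called by camera (adjusted p = 1.70e-07 and 1.92e-07, BH, against adjusted p = 0.346 and 0.45 with an estimated correlation), and medians that far from 0 argue against the trend as the whole cause. For oxidative phosphorylation the corrected median was 0.169 (0.125 to 0.226), still called by camera (adjusted p = 0.000629, BH, against an adjusted p of 0.860 with an estimated correlation). This met the rule set beforehand against the trend as the cause, a median above 0.15 and an adjusted p under 0.05. The interval, which that rule did not ask for, spans 0.15, so the share of the trend stays open. A smaller share of the outer gut wall would lower smooth muscle genes as well, and the gap between smooth muscle and the list was wider in MP_FOS by 0.297 for matrix and 0.378 for neurons, but by 0.107 and 0.0749 without MP_FOS replicate 3, by 0.140 and 0.243 without CT replicate 2 and, for matrix, by 0.449 without MP_FOS replicate 2. The libraries of the diets overlapped in both gaps, and so a difference in dissection and a biological change cannot be told apart.

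CD93, PTPRB and angiopoietin-2 may belong to a wider drop of endothelial genes. In a list of 25 other endothelial genes, 24 were lower in MP_FOS, with a median log2 fold change of −0.37, and MP_FOS replicates 1, 2 and 3 lay at −0.12, −0.66 and −0.49 against the CT mean. Camera gave an unadjusted p of 5.28e-07 with the preset correlation and 0.079 with an estimated one, which leaves the question open. MCAM, on vessel walls, and PROCR, the endothelial protein C receptor, were lower in DESeq2 (adjusted p = 0.03 and 0.0388, BH). Neither passed edgeR with all 6 libraries.

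The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The number of splits with as large a count, the real one included, with the real value and the highest of the other splits, was 10 for genes past the threshold in edgeR (0 and 1), 1 for genes with an unadjusted p under 0.05 (1457 and 1156), 1 for genes in DESeq2 (104 and 96), 6 for gene lists (9 and 12), 1 for KEGG pathways (28 and 27) and 1 for GO terms (186 and 82).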
